A study of Homo sapiens with 2 samples.

How the data were processed

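Total RNA was isolated from biopsies of the sigmoid colon, the last bend of the colon before the rectum. Per the labels, the authors pooled equal amounts of RNA from 5 healthy donors into a healthy pool and from 6 donors with ulcerative colitis (UC) into a UC pool, labelled each with biotin and hybridised it under the manufacturer's standard protocol. Each pool was read on 1 Affymetrix oligonucleotide array with 54675 probe sets. Pooling averages the donors before measurement, so the spread between donors is not in the data and a single donor with an extreme level can set a pool's value. Both groups were taken from the sample titles, no sample was left out, and the only comparison was UC pool against healthy pool.

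The deposited values are linear signal intensities, 1 per probe set and array, made with GCOS per the submitters' processing notes, with the version, the algorithm settings and the detection calls not given in the sources used here. The deposited intensities had the same mean on both arrays, 150.0, once the top and bottom 2% of probe sets were set aside, which shows that each array had been scaled to a common target. Such scaling removes any real difference in total RNA signal between the pools. The highest signals were 20824 on the healthy array and 16526 on the UC array. The 18 probe sets for hybridisation controls, bacterial and phage transcripts meant to be spiked into each sample, had a median log2 difference, UC minus healthy, of -0.22 (range -0.35 to -0.04). Only 1 of 54 values of the 27 poly-A control probe sets lay above the floor (highest signal 56.2), so these controls gave no check. The ratio of 3' to 5' signal, which rises when RNA is degraded, was 1.71 in the healthy pool and 1.55 in the UC pool for GAPDH, and 4.77 and 4.33 for ACTB. The 3 probe sets for 18S ribosomal RNA were lower in the UC pool by log2 differences of -0.41 to -1.05.

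Probe sets were named through the platform annotation of GEO, with symbols updated by gene ID to the RefSeq gene table of GRCh38.p14. Of all probe sets 41097 had 1 gene, 1801 had several and 11777 were not named here, and 41043 of the 41097 matched a gene ID in that table. No gene was named from a probe set with several genes. Among the named probe sets, 95 of certain sex-linked genes were left out of every table under a rule that protects donors. Genomic coordinates are not given, because no genome build applies to the deposited values.

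Signals below the pooled 40th percentile of both arrays (37.4) were set to that floor, and log2 was taken. Each gene was represented by its brightest probe set, which gave 19740 genes, 15391 of them above the floor on at least 1 array and 13258 on both. A difference is log2 signal in the UC pool minus that in the healthy pool, and genes were counted at 2-fold and 4-fold. Where 1 array was at the floor, the fold is a lower bound and is written as "at least". With 1 array per group no test was run. The spread among probe sets of the same gene covers probe design and hybridisation, and leaves out donors, sampling and RNA preparation. Differences across genes, which also hold biology, were wider for dim genes: their robust SD was 0.53 among the 4420 dimmest genes, 0.48 among those of middle signal and 0.44 among the 4419 brightest.

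Before the data were examined, 49 gene lists were fixed, covering inflammation, matrix, cell types, position along the colon, epithelial function, metabolism, cell state and technical controls, together with the rule for naming genes. The lists hold 840 distinct genes, of which 714 were measured above the floor on at least 1 array, 84 had no probe set of their own here and 40 are in more than 1 list. For each list the median difference of measured members was computed, with a 95% bootstrap interval over members (2000 draws) and its percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. A list of at least 4 members was called higher above the 97.5th percentile and lower below the 2.5th. Members of a list are not replicates, and an interval over members says nothing about other donors. For a difference between lists, members in both were left out and the interval was bootstrapped in the same way.

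The naming rule took the 15 largest differences in each direction among genes above the floor on both arrays whose probe sets all had the same sign, up to 5 genes per direction at the floor on 1 array, and up to 4 members per list with the largest differences measured on both arrays, plus members needed to describe a list's count or a check of cell composition. It named 205 genes, and DEFB1, CD177, ITLN1, CLCA4, CA4 and PLAC8 were added as exceptions within their lists, as were CFD, CXCL12 and ADAMDEC1. HK1, LDHA, ENO1, ALDOA and GAPDH were added as members of the glycolysis list under 2-fold.

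The alternatives were other scalings (median centring, quantile normalization, loess), a floor at the 25th or 60th percentile (signals of 17.2 and 81.4), a pseudocount at the 25th percentile in place of a floor, the mean over the probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at (which can cross-hybridise), the mean of list members, and list members held by no other list. Scaling to the hybridisation controls was added after seeing that these were dimmer on the UC array. The code was tested on simulated arrays with the real signal levels and noise as wide as the robust spread of the real differences, which includes real biological differences. The noise was drawn for each probe set on its own, so genes of a list did not vary together. There, 87.0% of 100 genes given a log2 change of 1.5 and 100.0% of 100 genes given 2.5 passed 2-fold. All of these genes were above the floor on both arrays with a mean signal above 149.4, so the rates do not cover dim genes. Of 20 simulated lists of 15 members shifted by 0.7, 20 were called higher, and 1 of 20 unshifted lists was called. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.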

Results

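Ulcerative colitis (UC) is a chronic inflammation of the mucosa of the colon, and the arrays address which transcripts differ in level between sigmoid colon of healthy donors and of donors with UC. RNA from biopsies of 5 healthy donors and of 6 donors with UC was pooled within each group, and each pool was read on 1 array, so every value below is the level in a pool and not in a person. The healthy array had a median signal of 55.9 array units and the UC array one of 54.3, with 60.5% and 59.5% of the 54675 probe sets above the floor, a signal of 37.4. There are no replicates, so no difference below has a replicate check or a p-value, the spread between donors is unknown, and the number of arrays limits the precision. The technical spread that could be measured was that among probe sets of the same gene, whose log2 differences had a pooled SD of 0.40 over 5911 genes.

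The UC pool had far higher signals of antimicrobial, neutrophil-related and matrix-degrading genes, and far lower signals of some genes of absorptive surface epithelium. S100A8, a subunit of the neutrophil protein calprotectin, had a signal of 68.6 in the healthy pool and 4397 in the UC pool, a 64.1-fold difference. DUOX2, an epithelial oxidase that makes hydrogen peroxide, was 38.9-fold higher, and MMP3, the metalloproteinase stromelysin, had signals of 47.4 and 1660. In the other direction AQP8, a water channel of surface colonocytes, had a signal of 6075 in the healthy pool and 305 in the UC pool, a 19.9-fold difference. ADH1C, an alcohol dehydrogenase, was 15.5-fold lower and CLDN8, a sealing claudin of tight junctions, was 12.9-fold lower.

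Of 15391 genes above the floor on at least 1 array, 886 (5.8%) were at least 2-fold higher in the UC pool and 639 (4.2%) at least 2-fold lower. At 4-fold the counts were 135 higher and 40 lower. For 218 of the 886 genes and 155 of the 639, the dimmer array was at the floor, so that their folds were lower bounds. Across the 13258 genes above the floor on both arrays, which are not independent replicates, Pearson's r of the log2 signals was 0.93, and the middle 95% of log2 differences ran from -1.14 to 1.33 around a median of -0.02. Of the 473 genes past 2-fold that had at least 2 probe sets above the floor on both arrays, 372 (78.6%) had all of them on the same side of 0. In a simulation whose noise was as wide as the robust spread of differences on these arrays, which leaves out their tails, 7.5% of unchanged genes passed 2-fold and 1.1% passed 4-fold, against 9.9% and 1.1% of genes on the arrays, so neither count can be read gene by gene. Among the 8083 genes with a mean signal above 149.4, 8.46% passed 2-fold on the arrays against 3.29% in the simulation, and 1.31% against 0.19% passed 4-fold. Higher genes made up 58.1% of the 2-fold differences with the deposited scaling, and 79.2% (1397 higher, 368 lower) when the arrays were scaled to their hybridisation controls, which moved the median of all genes to 0.19. That scaling assumes that both arrays received the same amount of these controls, which is not given in the sources used here.

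**Figure D1:**
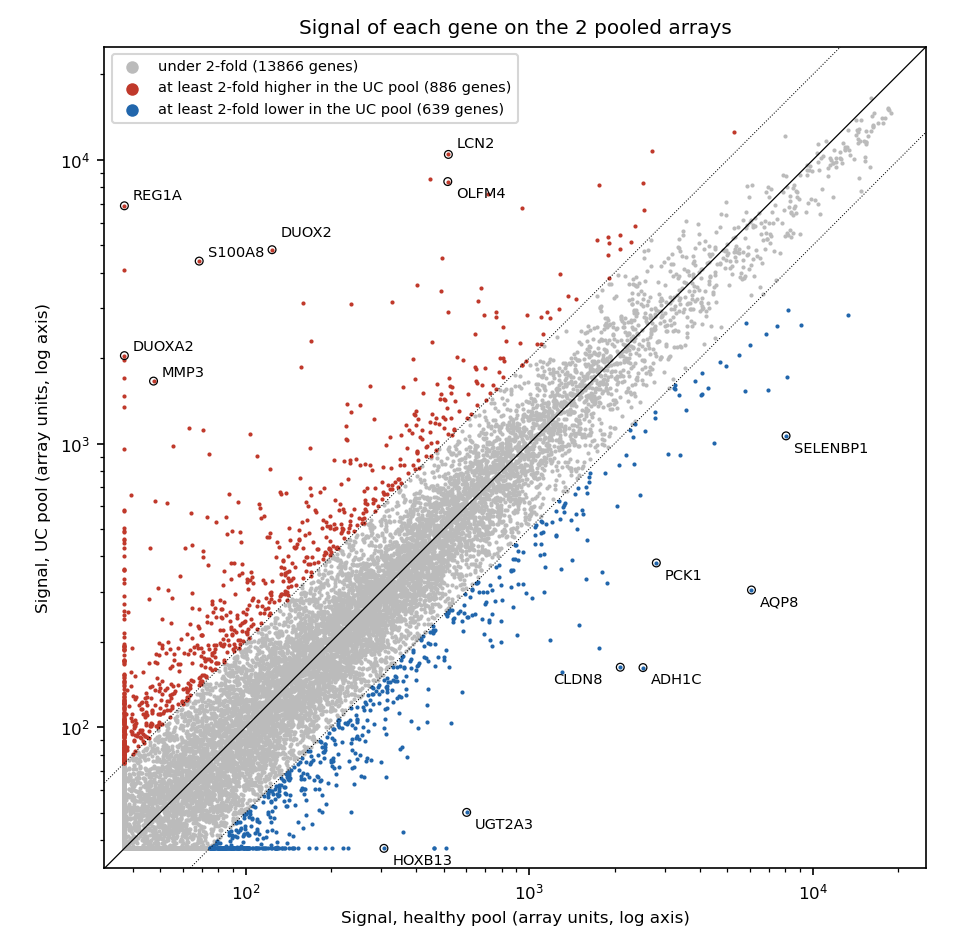
Signal of each of 15391 genes in the healthy pool (x axis, log scale, array units) and the UC pool (y axis, log scale, array units), with 1 point per gene, the line of equality and dotted lines at 2-fold. Points on the left and lower edges are at the floor of 37.4, red points are the 886 genes at least 2-fold higher, blue points the 639 at least 2-fold lower, and S100A8 and AQP8 lie at 64.1-fold and 19.9-fold.

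After S100A8, DUOX2 and MMP3, the 15 genes with the largest differences measured on both arrays were LCN2 (20.1-fold), CXCL8 (19.8-fold), PI3 (19.2-fold), VNN1 (17.99-fold), SERPINA3 (17.7-fold), IL1RN (16.7-fold), OLFM4 (16.2-fold), TCN1 (15.8-fold), DEFA5 (13.5-fold), CXCL1 (13.1-fold), NOS2 (13.0-fold) and MMP7 (12.3-fold). LCN2 is lipocalin-2, which withholds iron from bacteria, PI3 is the elastase inhibitor elafin, SERPINA3 is an acute-phase protease inhibitor and TCN1 is a vitamin B12 carrier of neutrophil granules. LCN2 was also among the brightest of them, at 519 in the healthy pool and 10453 in the UC pool. IL1RN had a second probe set with a smaller difference, 1.33 against 4.06 on the log2 scale. Genes at the floor in the healthy pool allowed only bounds. REG1A and REG1B, secreted lectins of the regenerating family, were at least 184-fold and at least 110-fold higher, DUOXA2, the maturation factor of DUOX2, at least 54.6-fold, the amino acid transporter SLC6A14 at least 52.6-fold, and the antibacterial lectin REG3A at least 45.7-fold.

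The 15 largest lower genes went on, after AQP8, ADH1C and CLDN8, with UGT2A3 (12.02-fold), CHP2 (9.26-fold), SLC6A19 (8.44-fold), MT1M (8.38-fold), SELENBP1 (7.56-fold), PCK1 (7.40-fold), ISX (6.58-fold), PADI2 (5.87-fold), TRPM6 (5.84-fold), ABCA8 (5.14-fold), SLC16A9 (5.12-fold) and NXPE4 (4.78-fold). UGT2A3 is a glucuronosyltransferase, SLC6A19 a neutral amino acid transporter, PCK1 the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, ISX an intestine-specific homeobox factor and TRPM6 a magnesium channel. SELENBP1, a selenium-binding protein, had a signal of 8044 in the healthy pool and 1064 in the UC pool. PADI2 had a second probe set at -0.44 against -2.55 on the log2 scale. Genes at the floor in the UC pool were RAPGEFL1 (at least 13.7-fold lower), CDHR1 (at least 12.4-fold, with another probe set at -1.51 on the log2 scale), CCDC13 (at least 12.3-fold), HOXB13 (at least 8.23-fold) and PNLIPRP2 (at least 6.17-fold). For CCDC13 another probe set differed by only -0.01, so its bound rests on a single probe set. Of the 15 largest differences, 11 of the higher and 13 of the lower genes also rested on a single probe set above the floor on both arrays.

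Of 49 gene lists, 24 had a median among the highest 2.5% of random lists of the same size and expression level. A further 13 had one among the lowest 2.5%, and 12 lay between. If each list were a random list, 2.5 lists would lie outside these limits. The lists share members, with 40 genes in more than 1, and genes of a list may vary together. That number is therefore no yardstick for these counts. The percentiles among random lists describe the 2 arrays and are not tests between patients and healthy people. Below, a list is called higher or lower by them, its median is given on the log2 scale with a 95% bootstrap interval over its members, and members are counted as at least 2-fold higher or lower.

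**Figure D2:**
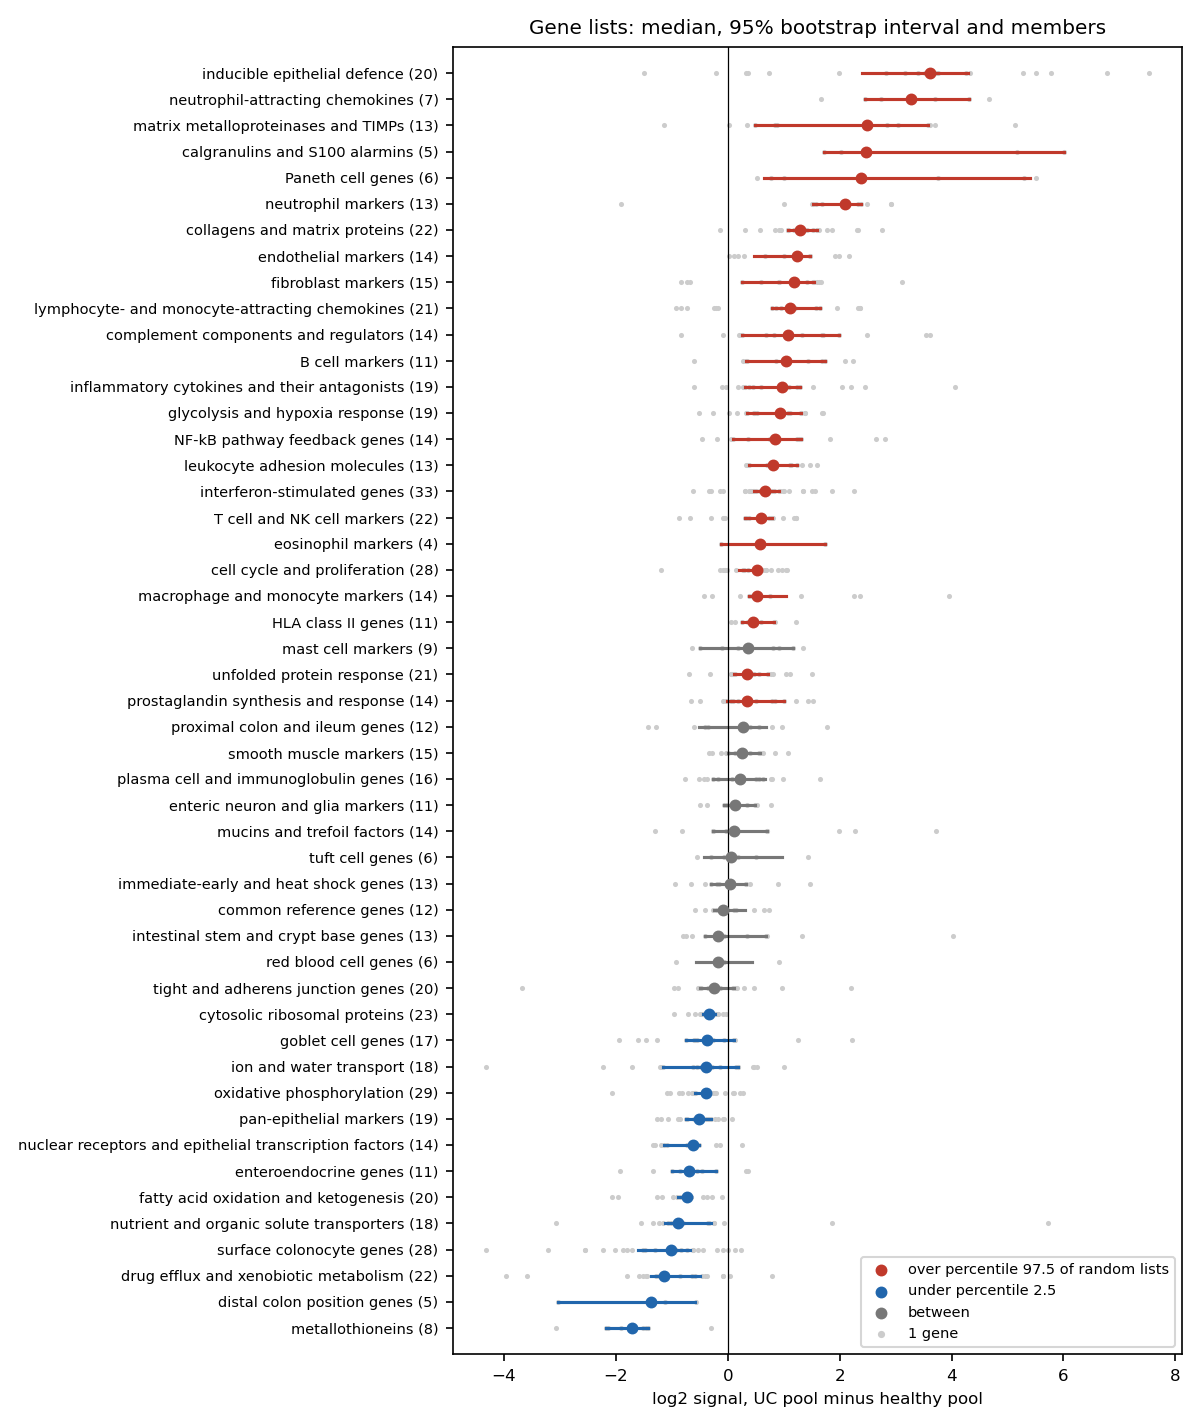
Median log2 signal difference, UC pool minus healthy pool (x axis), of each of 49 gene lists (y axis, number of measured members in brackets), with bars for the 95% bootstrap interval over members and small points for single genes. Lists run from inducible epithelial defence at 3.61 down to metallothioneins at -1.72, with 24 red (higher), 13 blue (lower) and 12 grey lists.

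Inducible defence genes of the epithelium gave the highest list median, 3.61 (2.41 to 4.30), with 15 of 20 measured members at least 2-fold higher and 1 at least 2-fold lower. They included DUOX2, LCN2 and PI3, and NOS2, the inducible nitric oxide synthase, at 47.9 in the healthy pool and 625 in the UC pool. The member that was lower was the constitutive beta-defensin DEFB1, with signals of 368 and 130. All 5 calgranulins and related S100 genes were at least 2-fold higher (median 2.48, 1.71 to 6.00), among them S100A11 at 2.03 and S100P at 1.71. All 6 measured genes of Paneth cells, the antimicrobial secretory cells that are usually scarce in the distal colon, were above 0 (median 2.38, 0.65 to 5.41) and 4 passed 2-fold. Among them the alpha-defensin DEFA5 had signals of 171 and 2305, the phospholipase PLA2G2A a difference of 1.01 and lysozyme, LYZ, one of 0.77 (another probe set at 2.66).

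Genes of inflammatory signalling were higher across most lists. All 7 chemokines that attract neutrophils were at least 2-fold higher (median 3.27, 2.46 to 4.31), with CXCL8 at 159 and 3142, CXCL1 at 3.71 and CXCL3 at 2.74. CXCL2 was at 2.46 with its brightest probe set and at -0.90 with the probe set left once those prone to cross-hybridisation were set aside. Of 21 chemokines that attract lymphocytes and monocytes, 12 were at least 2-fold higher and none at least 2-fold lower (median 1.11, 0.79 to 1.65), with CCL2 at 2.36, the B cell attractant CXCL13 at 2.35, CCL20 at 2.33 and CXCL10 at 1.95. Inflammatory cytokines and their antagonists had a median of 0.97 (0.31 to 1.29) with 9 of 19 at least 2-fold higher, led by the interleukin-1 receptor antagonist IL1RN and by IL1B, which had signals of 236 and 1292. Feedback genes of the NF-kB pathway had a median of 0.84 (0.10 to 1.32), with SOCS3 at 2.81 (another probe set at 0.12), TNFAIP6 at 2.65, SOCS1 at 1.83 (another probe set at -0.11) and CEBPB at 1.31. Complement genes were higher at 1.08 (0.26 to 1.995), with C4BPA at 3.55, CFI at 2.496, CFB at 1.995 and C5AR1 at 1.70. All 13 measured leukocyte adhesion molecules were above 0 (median 0.81, 0.39 to 1.23), and the largest differences measured on both arrays were those of VCAM1 (1.59), CD44 (1.33, with 10 probe sets from -0.15 to 1.96), ICAM1 (1.23) and ITGB2 (1.13).

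Interferon-stimulated genes and HLA class II genes were higher. The interferon list had a median of 0.66 (0.47 to 0.91), with 8 of 33 genes at least 2-fold higher, 25 under 2-fold and 5 below 0. Its largest differences were those of GBP1, a guanylate-binding protein (2.26), IFITM3 (1.87), the immunoproteasome subunit PSMB9 (1.56) and the tryptophanyl-tRNA synthetase WARS1 (1.502). All 11 class II genes, which serve antigen presentation, were above 0 but only HLA-DRA, at 1.21, passed 2-fold (median 0.44, 0.25 to 0.83). Without the probe sets prone to cross-hybridisation the class II median was 0.37 and no longer among the lists called higher.

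Matrix-degrading and matrix genes were both higher. Of 13 metalloproteinases and their inhibitors 7 were at least 2-fold higher and 1 at least 2-fold lower (median 2.49, 0.49 to 3.57), with MMP3 at 5.13, MMP7 at 3.62, the collagenase MMP1 at 3.57 and MMP9 at 3.04. Collagens and other matrix proteins had a median of 1.29 (1.07 to 1.60), and 16 of 22 were at least 2-fold higher. The matrix glycoprotein TNC (2.75) and COL12A1 (2.32) led among members measured on both arrays, each with a second probe set that differed less (0.06 and 0.45), followed by COL6A3 at 1.86 and COL4A1 at 1.78.

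Neutrophil markers were higher, and by more than those of macrophages or of T cells and NK cells. Of 13 measured neutrophil markers 12 were at least 2-fold higher and 1 at least 2-fold lower (median 2.09, 1.52 to 2.37). The median was 1.38 with the floor at the 60th percentile, and the 6 members at the floor in the healthy pool entered it as bounds. The immunoglobulin receptor FCGR3B was at 2.92, BCL2A1 at 2.92 and the formyl peptide receptor FPR1 at 2.48. The exception was CD177, which had a signal of 3406 in the healthy pool and 910 in the UC pool (-1.91). In the healthy pool it was far brighter than the other members, such as FCGR3B at 73.0, so whether it tracks neutrophils here is uncertain. Neutrophil markers lay above macrophage and monocyte markers by 1.57 (0.58 to 1.91) and above T cell and NK cell markers by 1.496 (0.80 to 1.98). Macrophage and monocyte markers had a median of 0.52 (0.38 to 1.03) with 4 of 14 at least 2-fold higher, among them SPP1 (osteopontin) at 2.36 and FCGR2A at 1.31. The T cell and NK cell median was 0.59 (0.31 to 0.79), with 4 of 22 at least 2-fold higher. GZMK was at 1.23, LCK at 1.22 (another probe set at 0.69) and CD8B at -0.88 (its 3 probe sets ran from -0.88 to 0.91).

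B cell markers were higher and plasma cell genes were not called. The B cell median was 1.04 (0.33 to 1.74), with BANK1 at 2.24 (another probe set at 0.33), MS4A1 (CD20) at 2.10, CR2 at 1.74 and PAX5 at 1.69, and 6 of 11 at least 2-fold higher. It was 0.34, and not called, without the probe sets prone to cross-hybridisation. Plasma cell and immunoglobulin genes had a median of 0.21 (-0.27 to 0.66), with POU2AF1 at 1.65, CD38 at 0.99 and MZB1 at 0.78, and the difference between both lists, 0.83 (-0.19 to 1.75), included 0. The 4 measured eosinophil markers were called higher at 0.58 (-0.12 to 1.74), led by CLC at 1.74, in an interval that held 0 and with a call that several other settings ended. Mast cell markers were not called (0.37, -0.49 to 1.17), although CPA3 was at 1.35 and the tryptase TPSAB1 at 1.16. Of the red blood cell genes HBB was at 0.92 and CA1, which colonocytes also express, at -0.92 (another probe set at 0.03), and the median was -0.17 (-0.57 to 0.42), not called.

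Vessel and fibroblast markers were higher, and muscle and nerve markers were not called. All 14 measured endothelial markers were above 0 and 9 were at least 2-fold higher (median 1.24, 0.47 to 1.47), with PECAM1 at 2.17, KDR at 1.99 and VWF at 1.46. The 5 probe sets of PECAM1 ran from -0.89 to 2.17. Fibroblast markers had a median of 1.17 (0.26 to 1.55), with LUM at 1.62, THY1 at 1.55 (another probe set at 0.31), WNT5A at 1.53 and COL1A2 at 1.41, and 8 of 15 at least 2-fold higher. Only 11 of the 15 were above the floor on both arrays. The 3 members below 0 were CFD (-0.84), CXCL12 (-0.73, another probe set at 0.42) and the bright gene ADAMDEC1 (-0.67, signals of 6181 and 3888). Smooth muscle markers were at 0.26 (0.00 to 0.58), with PLN at 1.07 and CALD1 at 0.85 (its 9 probe sets ran from -0.40 to 0.85), and enteric neuron and glia markers at 0.13 (-0.07 to 0.48). Endothelial markers exceeded smooth muscle markers by 0.98 (0.15 to 1.36), and fibroblast markers exceeded them by 0.92 (0.03 to 1.46).

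Epithelial genes were lower, those of surface colonocytes more than those of epithelium in general. Pan-epithelial markers had a median of -0.52 (-0.75 to -0.29), with 18 of 19 below 0 and 3 at least 2-fold lower: PHGR1 (-1.27), the intestinal transcription factor CDX2 (-1.20) and the splicing regulator ESRP1 (-1.07). CDX2 and ESRP1 each had another probe set under 2-fold, at -0.66. Surface colonocyte genes had a median of -1.01 (-1.60 to -0.68), and 14 of 28 were at least 2-fold lower. Besides AQP8 they included CHP2, a partner of sodium-proton exchangers, which had signals of 1757 and 190. PADI2 and TRPM6 were both at -2.55, with the 3 probe sets of TRPM6 from -2.55 to -1.25. The other 14 members were under 2-fold, 3 of them above 0. Among the 14, the bright genes CLCA4 (-0.19), CA4 (-0.08) and PLAC8 (0.01) hardly differed. The colonocyte median lay 0.48 below the pan-epithelial one (difference -0.48, -1.15 to -0.13, with shared members left out).

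Of the secretory lineages, enteroendocrine genes were lower at -0.69 (-0.997 to -0.21), with the peptide hormone PYY at -1.93, the serotonin-synthesis enzyme TPH1 at -1.33, SST at -0.997 and SCGN at -0.85. Goblet cell genes were lower at -0.37, in an interval that held 0 (-0.75 to 0.11), and its members lay on both sides of 0: WFDC2 was at -1.94, KLK1 at -1.60 and GALNT12 at -1.46, while SPINK4 had signals of 1756 and 8144 (2.21) and ITLN1, intelectin-1, was at 1.25. The goblet call was lost when probe sets of a gene were averaged (-0.29) and without those prone to cross-hybridisation (-0.28). The differences from pan-epithelial markers, 0.15 (-0.36 to 0.64) for goblet genes and -0.16 (-0.61 to 0.38) for enteroendocrine genes, had intervals that included 0. Tuft cell genes, at 0.06 (-0.43 to 0.97), and genes of stem cells and the crypt base, at -0.17 (-0.40 to 0.67), were not called. The stem cell list had a mean of 0.29, opposite in sign to its median, and its highest members were OLFM4, with signals of 516 and 8386, and CD44 at 1.33.

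**Figure D3:**
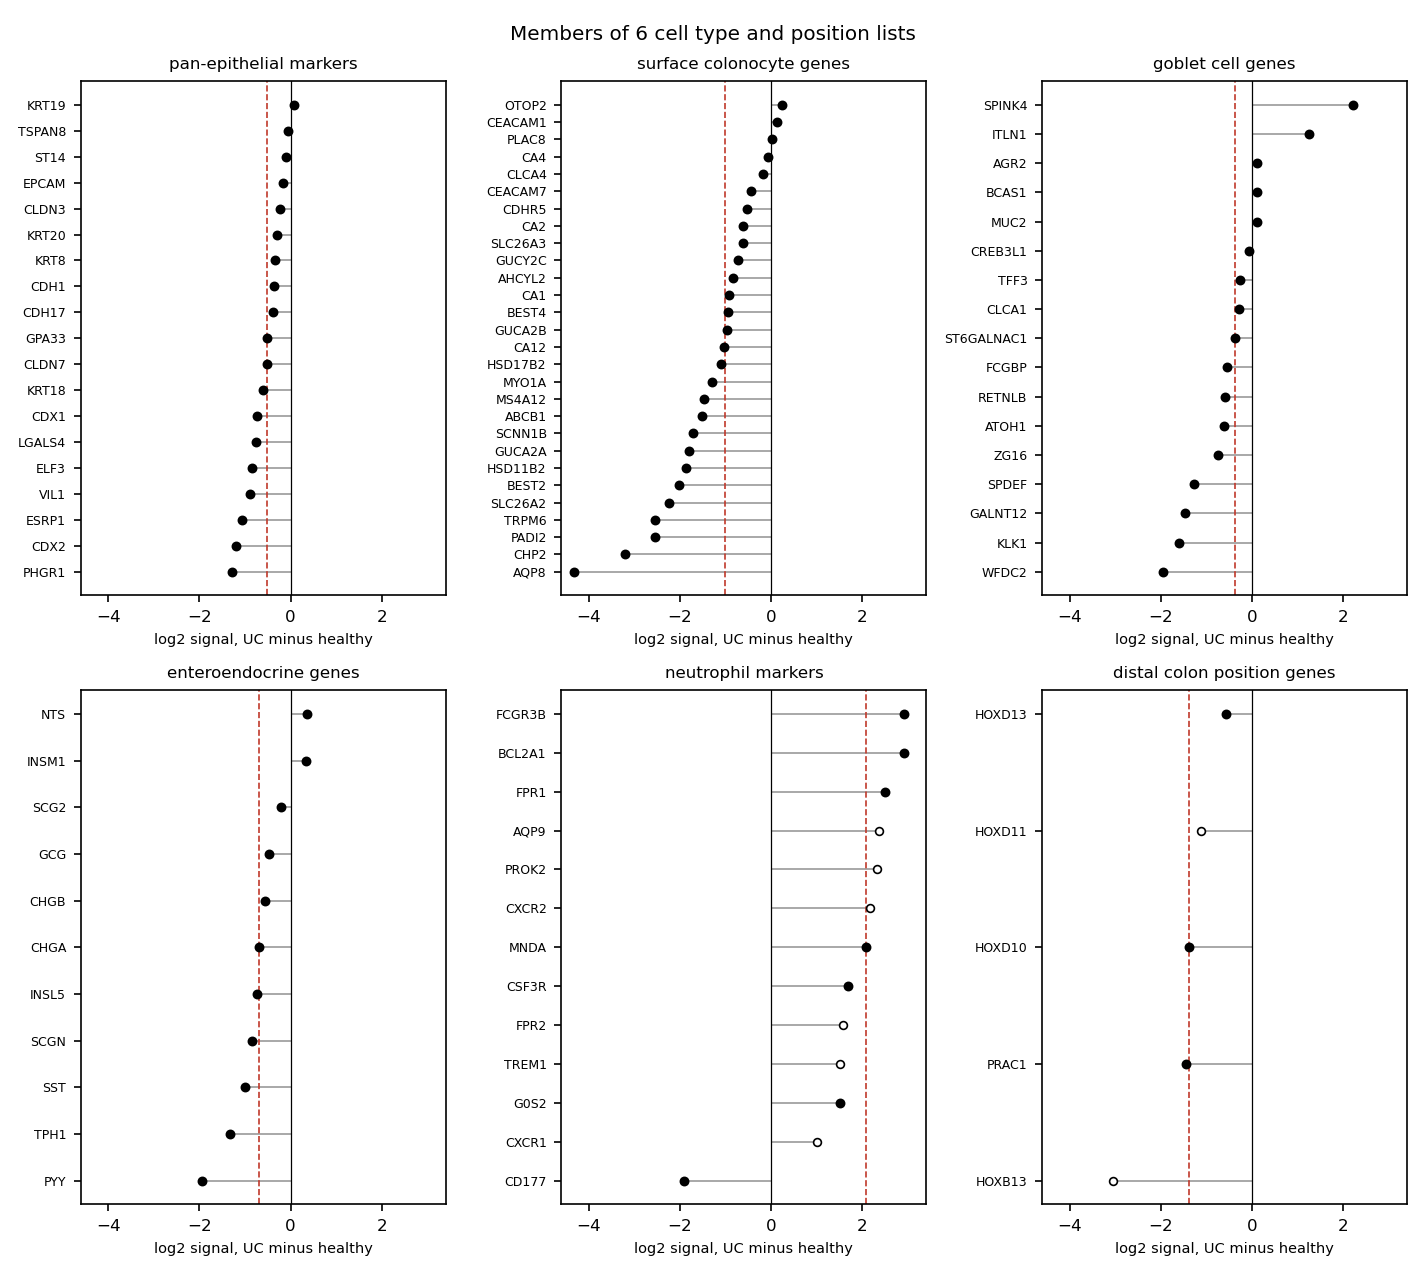
Log2 signal difference, UC pool minus healthy pool (x axes), of each measured gene (y axes) in 6 lists, with filled circles for genes above the floor on both arrays, open circles for genes at the floor on 1 array, and a dashed line at the list median. Medians are -0.52 for pan-epithelial, -1.01 for surface colonocyte, -0.37 for goblet, -0.69 for enteroendocrine, 2.09 for neutrophil and -1.38 for distal colon position genes.

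Transport and detoxification genes of the epithelium were lower. Drug efflux and xenobiotic metabolism genes had a median of -1.15 (-1.37 to -0.49), with 12 of 22 at least 2-fold lower, among them ADH1C, UGT2A3, the efflux pump ABCG2 (-1.81) and the epoxide hydrolase EPHX2 (-1.58). Nutrient and organic solute transporters had a median of -0.89 (-1.12 to -0.30) with 7 of 18 at least 2-fold lower and 2 at least 2-fold higher. SLC6A19 (-3.08) and the bile acid transporter subunit SLC51A (-1.56) were lower, and SLC6A14 and the cystine transporter SLC7A11 (1.86) were the higher members. Ion and water transport genes had a median of -0.39 (-1.16 to 0.18), in an interval that held 0, with AQP8 at -4.32, the sulfate transporter SLC26A2 at -2.24, the sodium channel subunit SCNN1B at -1.72 and SLC4A4 at -1.21. Restricted to members that no other list holds, this median was 0.007 and the call was lost. Nuclear receptors and epithelial transcription factors were lower at -0.63 (-1.14 to -0.51). PPARG was at -1.35, FOXA2 at -1.31 (another probe set at -0.71), CDX2 at -1.20 (another at -0.66) and the vitamin D receptor VDR at -1.14 (another at -0.11). Pan-epithelial markers, which share members with this list, were at -0.52 (-0.75 to -0.29). No difference from them was computed for the lists of this paragraph.

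Metallothioneins, small zinc- and copper-binding proteins, gave the lowest list median, -1.72 (-2.17 to -1.42), and 7 of 8 were at least 2-fold lower. MT1M was at -3.07, MT1G had signals of 6932 and 1539, MT1F was at -2.15 and MT1H at -1.92. Metallothioneins lay below pan-epithelial markers by more than the interval of the difference (-1.20, -1.80 to -0.72). These genes are close paralogs, so their probe sets can share signal and the 8 values are not independent.

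Mitochondrial energy genes were lower, and the joint list of glycolysis and hypoxia genes was higher. All 20 measured genes of fatty acid oxidation and ketogenesis were below 0 (median -0.72, -0.88 to -0.66), with the mitochondrial regulator PPARGC1A at -2.07, ACSF2 at -1.97, ACAT1 at -1.27 and ACADS, which oxidises short-chain fatty acids such as butyrate, at -1.17. Oxidative phosphorylation genes were lower at -0.40 (-0.58 to -0.34), with 25 of 29 below 0 and UQCRC1 at -1.09. That fall was no larger than the one of pan-epithelial markers, at -0.52 (-0.75 to -0.29). Fatty acid oxidation lay below oxidative phosphorylation by 0.32 (difference -0.32, -0.48 to -0.14), whereas its difference from pan-epithelial markers, -0.20 (-0.51 to 0.06), included 0. Glycolysis and hypoxia genes had a median of 0.92 (0.35 to 1.31), and 8 of 19 were at least 2-fold higher, with the hypoxia-induced peptide ADM at 1.70, the glycolytic regulator PFKFB3 at 1.69, PKM at 1.38 (another probe set at -0.37) and SLC2A3 at 1.38. The other 11 were under 2-fold. Among them were the glycolytic enzymes HK1 (0.99), LDHA (0.47), PGK1 (0.47), ENO1 (0.35), ALDOA (0.16) and GAPDH (-0.27), so glycolytic genes did not rise alike.

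Genes that mark the distal end of the colon were lower in the UC pool. All 5 measured members were below 0 and 4 were at least 2-fold lower (median -1.38, -3.04 to -0.58). HOXB13, a homeobox gene of the most distal gut, had a signal of 308 in the healthy pool and was at the floor in the UC pool. PRAC1, a gene of the distal colon and rectum, had signals of 4063 and 1492 (-1.45), HOXD10 was at -1.38 and HOXD13 at -0.58. Genes of the proximal colon and ileum were not called (0.27, -0.51 to 0.68), with 7 above 0 and 5 below, among them HOXD4 at -1.28 and APOA1 at 0.56. The list also holds OSTC (0.97), a subunit of the oligosaccharyltransferase complex that does not mark position.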

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

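Signals outside the gene table, in probe sets that the comparisons of genes do not use, also differed between the pools. Of 13486 such probe sets, which have several genes or no gene named here, with control probe sets and those of sex-linked genes left out, 7719 were above the floor on at least 1 array, and 17 were at least 4-fold higher in the UC pool and 15 at least 4-fold lower. Among probe sets assigned to several genes, the largest higher difference measured on both arrays was that of a probe set assigned to 2 genes, with signals of 183 and 1660 (log2 difference 3.18). The brightest of those at least 2-fold higher was assigned to 5 genes, with signals of 3675 and 14468 (1.98). Such a probe set cannot say which of its genes differed, and no explanation was tested for these results.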

How the results depend on the processing

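The 11 alternatives include 1 chosen after seeing the data, scaling to the hybridisation controls. Of 37 lists called higher or lower, 30 kept their call and direction under all alternatives that gave a percentile, and 7 lost one or the other under at least 1. Below 4 members no percentile was computed, which affected eosinophil markers and distal colon genes at the floor of the 60th percentile and metallothioneins without _x_at and _s_at probe sets. Of the 12 lists without a call, 3 gained one under at least 1 alternative: junction genes as lower under 7 (-0.35 to -0.03), mast cell markers as higher under 2 (0.59 and 0.81) and mucins under 1 (mean of members, 0.51). CXCL2 reversed, to -0.90, without _x_at and _s_at probe sets, a setting that gave a value for 153 of 205 named genes, and 200 had one at the 60th percentile floor. No other named gene reversed where it had a value, but values moved by more than 0.40 for 40 genes with the mean over probe sets, 31 at the 60th percentile floor, 10 without _x_at and _s_at probe sets, 9 at the 25th percentile floor and 5 with the pseudocount. Where a cause is not named below, the cause was not tested.

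The counts at 2-fold followed the floor by construction: 1412 higher and 1166 lower at the 25th percentile, 564 and 362 at the 60th. Hybridisation control scaling gave 1397 and 368. It moved the median of all genes from -0.02 to 0.19, by adding a constant, and the other medians of all genes were 0.016 with median centring, 0.000 with quantile normalization, 0.030 with loess, -0.041 with the mean over probe sets and -0.031 without _x_at and _s_at probe sets. The same constant moved T cell and NK cell markers to 0.81, fatty acid oxidation to -0.50, oxidative phosphorylation to -0.18, nuclear receptors to -0.41, proliferation to 0.75 and ribosomal proteins to -0.11, with every call kept.

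Eosinophil markers, with 4 members, lost their call with median centring (0.61), the floor at the 25th percentile (0.81) and the pseudocount (0.69). Ribosomal proteins lost theirs with quantile normalization (-0.10), loess (-0.12) and without _x_at and _s_at probe sets (-0.35). The last setting, which leaves fewer members, also ended the calls of HLA class II genes (0.37), prostaglandin genes (0.22), B cell markers (0.34) and goblet cell genes (-0.28). Goblet cell genes lost theirs with the mean over probe sets too (-0.29), which moved collagens to 0.97 with the call kept. Neutrophil markers moved to 1.38 at the 60th percentile floor, which shortens folds of dim genes, with the call kept. Limited to members of no other list, prostaglandin genes were at 0.074 without a call, and ion and water transport genes turned to 0.007. Signal over background limits the dim genes most, since folds at the floor are bounds.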

Other observations

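Tests of the macrophage genes alone and of the distal colon genes were chosen after those results were seen, as was the limit that the blood test of the neutrophil genes applies, and the others before. Another rule set beforehand concerned deeper biopsies in 1 pool. It asked whether smooth muscle and nerve lists lay on the same side of 0 or on opposite sides, with intervals that leave out 0. The intervals, 0.00 to 0.58 and -0.07 to 0.48, met neither outcome. Biopsy depth therefore stays open for the higher fibroblast and vessel genes.

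Genes of cell division and of the endoplasmic reticulum stress response were modestly higher in the UC pool. Proliferation genes had a median of 0.53 (0.21 to 0.60), with 20 of 28 above 0. RRM2 was at 1.06 and the kinase CDK1 at 1.03 (its 3 probe sets ran from 0.40 to 1.03), while AURKB was at -1.19 (another probe set at -0.78). Of 21 genes of the unfolded protein response 19 were above 0 (median 0.35, 0.11 to 0.72), with TRIB3 at 1.499, CRELD2 at 1.12 and the chaperone HSP90B1 at 1.03 (another probe set at 0.23). Immediate-early and heat shock genes, which can respond to handling of a biopsy, were not called (0.04, -0.31 to 0.33), with HSPA6 at 1.46 (another probe set at 0.21) and EGR1 at -0.95. Genes of prostaglandin synthesis and response were called higher at 0.34 in an interval that held 0 (-0.01 to 1.01), with PTGES at 1.53, ALOX5 at 1.44 (its 3 probe sets ran from -0.22 to 1.44) and PTGS2 (COX-2) at 1.22. That call ended without _x_at and _s_at probe sets (0.22) and with members of no other list (0.074).

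Barrier genes held large opposite differences under medians near 0. Mucins and trefoil factors were not called (0.11, -0.27 to 0.71), with MUC17 at 2.26 (another probe set at -0.03), the gastric trefoil peptide TFF1 at 1.996, MUC12 at -1.30 and MUC20 at -0.83. Junction genes were not called either (-0.25, -0.50 to 0.12), though 7 alternatives called them lower, yet CLDN8 had signals of 2094 and 163 and CLDN1 signals of 64.7 and 297. The pool with lower CLDN8 thus had higher CLDN1, at -3.69 and 2.20, and CLDN12 was at 0.96. Cytosolic ribosomal proteins were all below 0 and under 2-fold (median -0.33, -0.44 to -0.23), a call that quantile and loess scaling ended, and common reference genes lay at -0.08 (-0.25 to 0.31), positive under quantile, loess and hybridisation control scaling.

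The lower surface colonocyte genes may reflect loss of part of the absorptive program beyond a smaller share of epithelium, as a hypothesis. Such a loss was not shown to be particular to absorptive cells. The colonocyte median minus the enteroendocrine one was -0.32 (-1.10 to 0.07), an interval that included 0. A smaller share alone would lower all epithelial genes about alike. The colonocyte median lay below the pan-epithelial one, with an interval of the difference that left out 0 (-0.48, -1.15 to -0.13). That interval runs over genes, which are not replicates, and says nothing about other donors. Lower RNA integrity in a pool would need the 3' to 5' ratios to differ, and both differed by a factor of 1.10. Median centring, quantile and loess scaling left the list median between -1.05 and -0.97, and scaling to the hybridisation controls gave -0.79. None of these scalings removed the difference. All but the last keep the centres of both arrays close, as the deposited scaling does, so they could hardly have removed it. A smaller epithelial share as part of the cause stays open, since pan-epithelial markers were lower too, as does a loss of surface cells relative to crypt cells. Surface genes differed among themselves, with 14 of 28 at least 2-fold lower and 14 under 2-fold, CLCA4 at -0.19 and CA4 at -0.08 among the latter.

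Higher neutrophil genes could come from blood in the biopsies. The test takes blood of both pools to hold neutrophils and red cells in the same proportion, which was not measured. Blood alone would then need HBB to be higher by at least as much as the neutrophil median of 2.09 (1.52 to 2.37). HBB was at 0.92, with its 4 probe sets between 0.92 and 1.26. HBD (-0.13, signals of 132 and 121) and AHSP (-0.07, signals of 59.6 and 56.9) were dim, so they say little. With unlike proportions, blood alone is not excluded. The neutrophil median was 1.38, nearer to HBB, at the 60th percentile floor, which shortens folds of dim genes by construction. The value set beforehand to exclude blood, a median of 0 or below over HBB and other globin genes that had no probe set of their own here, was not met by HBB, so more blood in the UC pool stays open as a part of the cause, and that value was too strict for a test of the whole cause. For macrophage genes alone (0.52, 0.38 to 1.03) the HBB range overlaps the interval, so that blood and tissue cells cannot be told apart there. The neutrophil median was at least 2.115 and the macrophage median at least 0.529 under median centring, quantile and loess scaling. Both were higher still with the hybridisation controls, so none of these scalings removed either rise. Median centring, quantile and loess scaling left the median of all genes between 0.000 and 0.030, near the -0.019 of the deposited scaling. They had little room to move a list median, and so they are no strict test of scaling.

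Lower distal colon genes may be a sign of altered positional identity, a hypothesis that was not tested, or of biopsies from a different level of the colon. A smaller share of epithelium would lower them about as much as pan-epithelial markers, and the difference from those was -0.86 (-2.52 to -0.05), an interval that rests on 5 genes and comes close to 0. Biopsies from a more proximal site in the UC pool would raise proximal genes, whose median of 0.27 had an interval from -0.51 to 0.68, so site and disease cannot be told apart for these genes. The proximal list is also a weak gauge of site, since it holds OSTC, which does not mark position. Median centring, quantile and loess scaling left the distal median at or below -1.318, and scaling to the hybridisation controls gave -1.16. The labels give sigmoid colon for both pools, without the level within it or whether the UC mucosa was inflamed, and the site stays open.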
